A study of Mus musculus with 16 samples.

How the data were processed

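Total RNA from whole kidneys of mouse embryos at embryonic day 17.5 was hybridised to 16 Agilent whole-genome oligonucleotide arrays with 2 dyes. The labels give 4 genotypes with 4 arrays each: control, conditional Ezh2 knockout in Six2-positive nephron progenitors with wild-type Ezh1 (called the Ezh2-KO group), the same with 1 germline Ezh1 allele lost (the Ezh1-het group), and the same with both lost (the double knockout). The group and the replicate number of each array were taken from the sample titles and genotype labels. Per the labels, each array carried the sample in Cy5 and RNA of control 1 in Cy3, and no dyes were swapped. The array of control 1 therefore compared that RNA with itself and was kept as a control replicate. The labels name the arrays biological replicates, and p-values measure the spread between these samples.

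Per the file headers, the deposited intensity columns came from Agilent Feature Extraction 10.7.3.1, the version that the submitters' processing notes also give. They hold raw median spot and background intensities, and processed intensities that the software had background-subtracted and dye-normalised within each array. The deposited log10 ratio column is the log10 of processed Cy5 over processed Cy3. The authors' value table held that log10 ratio rounded, with a difference of at most 0.005 on every array. The median of each of its 16 columns was 0 on the log10 scale, so its scale, centring and direction were those of the software's own ratio, and none of the 3 stayed unknown.

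The array holds 62976 features, of which 3671 are control features and 59305 carry 56605 distinct probes. The files name probes by accession only, so symbols were taken from a RefSeq gene table (assembly GRCm38.p6), ignoring accession versions. Of 29638 probes with a RefSeq mRNA accession 29339 matched, and 32994 probes received 1 symbol (22911 symbols). The remaining 23611 probes stayed unnamed and none had several symbols. The array grid was annotated on mm9, so no coordinates are given, and positions of probes within transcripts were not used here.

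Median spot intensities were background-corrected with normexp (offset 50) over all spots and normalised within each array by loess, with control spots at weight 0 and outlier-flagged spots left out, in limma 3.58.1 under R 4.3.3. The files hold median and not mean spot signals, which the design had named, so medians were used throughout. Spots of 1 probe were averaged. Probes were kept if they were well above background in Cy5 on at least 4 of the 16 arrays (34731 probes, 22862 with a symbol). The probe with the highest mean intensity over all arrays stood for its gene, which gave 15646 genes tested. Of the 99 genes named under the rule stated here, 31 had more than 1 probe that passed the filter, and for 5 of them (Wdfy1, Ibtk, Zfyve1, Foxm1 and Aebp2) the probes differed in sign between double knockout and control.

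Signal limits the precision of dim probes. The 75th percentile of Cy5 signal over background ran from 5.23 on control 2 to 16.6 on Ezh2-KO 4, and 53.1% to 63.4% of probes were well above background in Cy5, the lowest share again on control 2. No spot was saturated, and 69 to 343 spots per array were outlier-flagged and left out. Number of arrays limits the precision of every group mean. The arrays lie on 2 slides, each with 2 arrays of every genotype, and scans were split the same way. Slide 1 holds replicates 1 and 2, and slide 2 replicates 3 and 4. Because every group lies on both slides in equal number, a slide block leaves each difference and list shift as it is and changes only its error.

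Group differences in log2(Cy5/Cy3) were tested with limma's lmFit and eBayes in 1 fit of all 16 arrays, without covariates, and adjusted by Benjamini-Hochberg within each comparison (threshold 0.05). All tests were two-sided. All adjusted p-values of genes come from this limma model. The log2 differences are given with the model's standard error (SE), n = 4 per group. A further fit took the number of Ezh1 alleles lost as a linear term over the 12 Ezh2-deficient arrays. Where no array of a group had a probe well above background, the fold is a bound written as "at least". It sets the bright group's mean Cy5 level against, per array of the dim group, the higher of the lowest Cy5 level of any probe well above background and the probe's own. This was done after loess and Aquantile scaling in the Cy5 channel alone, and is open to dye bias because no dyes were swapped. Where the fold of the Cy5/Cy3 ratio was smaller than that value, the smaller of the 2 is printed after "at least". The words refer to the background limit alone. They are not a limit of the sampling error, which the SE gives.

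Lists of genes were tested with camera (preset correlation 0.01), with an estimated correlation and fry as alternatives, and adjusted over the 25 lists that had at least 5 measured members. The 26 lists were PRC2 subunits, nephron progenitor, early nephron, podocyte, proximal tubule, loop of Henle and distal tubule, ureteric bud and collecting duct, stroma, endothelium, macrophage and immune, erythroid, adrenal, gonad, liver, skeletal muscle, nerve, Hox genes, lineage transcription factors outside the kidney, CDK inhibitors, proliferation, p53 targets, Wnt/beta-catenin targets, germline, immediate early and heat shock, tubular injury, and sex-linked genes. They held 565 entries, 564 with a symbol in the reference, and 14 genes stood in more than 1 list. A list shift is the mean log2 difference of its members minus that of the other genes.

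The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Named in every comparison were Ezh2, Ezh1, Six2, Cited1, Wnt4, Lhx1, Cdkn2a and Cdkn2b. In the comparisons against control and of double knockout against Ezh2-KO, the rule added the 8 largest rises and 8 largest falls among called genes with a symbol whose 4 and 4 arrays did not overlap, leaving out predicted transcripts, and up to 3 called members of each list with the smallest p. Values of some genes that the rule named are not reported here. Other genes are said to have been chosen after their values were seen.

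Alternatives covered no background subtraction, the software's processed signals, the value table, median centring in place of loess, Aquantile scaling, the Cy5 channel alone, other filters on dim probes, other rules for probes of a gene, the slide as a fixed or random block, the replicate number as a block, only the groups compared, eBayes with trend and robust variance, array weights, a fold minimum of 1.5, and each array left out in turn. Fits without control replicates 2 and 3, and with the immediate early score as a covariate, were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9, and random blocks used statmod 1.5.0.

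The fit was tested on simulated data for double knockout against control, with 15646 genes and 200 changed by known sizes. It called 22 of 50 genes changed by 0.5 on the log2 scale, 46 of 50 changed by 1, 50 of 50 changed by 2 and 50 of 50 changed by 3, with mean estimates of 0.46, 0.99, 2.03 and 3.02. Of its 174 calls 6 were false. Noise was drawn for each gene on its own with the same spread in every group. Deviations of an array that many genes share were therefore not simulated, and these shares need not hold for the real arrays. The 23611 unnamed probes entered only the count of probes tested separately.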

Results

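The series asks how whole-kidney expression at embryonic day 17.5 differs when Ezh2, a methyltransferase of the Polycomb complex PRC2, is deleted from Six2-positive nephron progenitors, and when germline loss of the related methyltransferase Ezh1 is added. The 16 arrays fall into control, Ezh2-KO with wild-type Ezh1, Ezh1-het (Ezh2-KO with 1 Ezh1 allele lost) and double knockout, with 4 arrays in each group. Every array measured its sample in Cy5 against the same control RNA in Cy3, and values are log2 differences with SE at n = 4 per group. Whole kidneys mix cell types, so a value averages over the deleted progenitors and all others. Control 2 had the weakest Cy5 signal, and control 3 lay farthest out on the first principal component, which held 36.1% of the variance (scores of 37.3 for control 3 and 31.4 for Ezh2-KO 1). The fits were therefore repeated without these controls.

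The targeted genes followed the labels for Ezh1. Its level was -4.55 ± 0.08 (SD, n = 4) in the double knockout and -1.13 ± 0.20 in the Ezh1-het group, against -0.08 ± 0.26 in controls and 0.05 ± 0.33 in Ezh2-KO. Ezh1 fell by 4.47 (SE 0.15, limma adjusted p = 5.46e-11, 22.2-fold) in the double knockout and by 1.05 (SE 0.15, adjusted p = 0.000912) in the Ezh1-het group, in which the call was lost with median centring and with trend and robust variance. The log2 difference in Ezh2-KO was 0.12 (SE 0.15, adjusted p = 0.650). Of the 5 Ezh2 probes, A_51_P248067 differed by -3.41, -3.53 and -3.19 (SE 0.21 each) in Ezh2-KO, Ezh1-het and double knockout, leaving 9.39%, 8.66% and 10.99% of the control signal. The brightest Ezh2 probe, which stood for the gene in the tests, differed by -0.27, -0.34 and -0.22 (SE 0.13 each, adjusted p of 0.237, 0.119 and 0.419), and these values were positive with median centring. In that setting the double-knockout value of 0.33 passed the threshold (limma adjusted p = 0.0484). A probe outside the deleted part checks nothing, and which probes lie inside it was not analysed here.

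In Ezh2-KO kidneys the largest rises against control were in S100a9, Miat, Cstdc5, Bcl11a, Stfa1, Lin28b, S100a8 and Fbln2. Lin28b, an RNA-binding inhibitor of let-7 maturation, was at least 3.79-fold higher (1.92, SE 0.12, adjusted p = 4.28e-07), and the zinc-finger repressor Bcl11a rose by 1.97 (SE 0.13, 3.92-fold, adjusted p = 4.28e-07). The long non-coding RNA Miat rose by 2.12 (SE 0.29) and the matrix protein Fbln2 by 1.61 (SE 0.20). Miat values in Ezh2-KO were 2.27 and 2.11 on slide 1 and 0.83 and 1.15 on slide 2, while those of Bcl11a ran from 1.74 to 1.99. The progenitor gene Cited1 fell by 0.69 (SE 0.13, adjusted p = 0.0104), a call lost with median centring, where the value was -0.15, and with trend and robust variance. Six2, the marker of self-renewing progenitors, was at -0.07 (SE 0.26, adjusted p = 0.900), Wnt4 at 0.27 (SE 0.16, adjusted p = 0.329) and Lhx1 at 0.01 (SE 0.31, adjusted p = 0.985).

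Among genes whose arrays did not overlap, the falls were led by the nuclear receptor gene Nr1h5 (at least 2.55-fold lower, adjusted p = 6.23e-05), Wdfy1 (-1.31, SE 0.19), the calcium-binding Ocm (-1.05, SE 0.13), Cyth3, Hoxb5os (-0.91, SE 0.14), Fat3, Ibtk and Zfp931. Another probe of Wdfy1 fell by 1.10, and the last of its 3 was at 0.01. The estimate for the cell-cycle inhibitor Cdkn2a was at least 2.36-fold above control in the sense defined above, but short of the threshold (1.24, SE 0.33, adjusted p = 0.0520). Its values were 0.15 and 0.61 on slide 1 and 2.01 and 2.08 on slide 2. Cdkn2a was well above background on 3 of the 4 Ezh2-KO arrays and on 0 of 4 controls. A dimmer Cdkn2a probe differed less, by 0.04 in Ezh2-KO, 0.65 in Ezh1-het and 0.92 in the double knockout. Its neighbour Cdkn2b was at 0.73 (SE 0.22, adjusted p = 0.0845), with values of 0.08 and 0.27 on slide 1 and 0.97 and 1.08 on slide 2.

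Of the Wnt/beta-catenin targets 4 of 17 measured members rose in Ezh2-KO (6 adjusted over the list alone), among them the secreted Wnt antagonist Wif1 (0.77, SE 0.11), Nkd1 (0.59, SE 0.11) and Apcdd1 (0.42, SE 0.09). The list was called upwards (camera adjusted p = 0.00180, but adjusted p = 0.1998 with an estimated correlation). These 3 genes are known both as targets and as inhibitors of the pathway. Its shift was 0.24 on slide 1 and 0.35 on slide 2. Proximal tubule genes as a list were lower (camera adjusted p = 0.00180, adjusted p = 0.954 with an estimated correlation), but their shift was -1.49 on slide 1 and 0.60 on slide 2, and 0 of 29 members passed limma's threshold (0 adjusted over the list alone), where 3329 genes had an unadjusted p under 0.05. Early nephron (1 of 24 rose, Npy, 6 over the list alone), proliferation (1 of 34, Foxm1, 1 over the list alone) and immediate early and heat shock genes (1 of 16, Ier3, 4 over the list alone) were called upwards with camera adjusted p of 0.0400, 0.00401 and 0.0225. These 3 had adjusted p = 0.954 with an estimated correlation, and shifts of -0.21 and 0.72, 0.17 and 0.10, and 0.64 and 0.25 on slides 1 and 2. The proximal tubule call ended without control 2 (adjusted p = 0.174) or Ezh2-KO 1 (0.157), proliferation without control 2 (0.123) or Ezh2-KO 3 (0.116), immediate early without Ezh2-KO 1 (0.202), Ezh2-KO 2 (0.0936) or control 4 (0.343), and early nephron without control 3 (0.643), Ezh2-KO 3 (0.161) or 4 (0.123) and with the slide or the replicate number as a block (0.0551 and 0.0655). Other single arrays moved shifts the other way. Without control 3 or Ezh2-KO 4 the proximal tubule shift was -0.86 or -0.73 in place of -0.44, and without Ezh2-KO 1 the early nephron shift was 0.39 in place of 0.25. The rise of Dlk1 (1.04, SE 0.21), Meis1 (0.80, SE 0.17) and renin, Ren1 (0.70, SE 0.12), made 3 of 22 stroma genes. In the nephron progenitor list 3 of 22 fell and 1, Lypd1 (at least 1.33-fold higher, adjusted p = 0.00927), rose.

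In all, 482 of 15646 genes differed between Ezh2-KO and control, 376 higher and 106 lower (limma, adjusted p under 0.05), and 220 of them by at least 1.5-fold. With only the 2 groups fitted the count was 59, and with array weights 879. Another split of the same 8 arrays into 4 and 4 gave 654 genes. The arrays of both groups did not overlap for 11.2% of genes, where chance gives 2.86%. Leaving out control 2, Ezh2-KO 2 or Ezh2-KO 4 gave 204, 201 and 265 genes, and the fit without controls 2 and 3 gave 78. With the slide as a block 608 genes differed, within slide 1 and slide 2 alone 162 and 6, and the differences on the 2 slides correlated across genes at -0.04 (Spearman 0.13), genes not being independent replicates. With median centring the median log2 difference of all genes was 0.41 in this comparison, 0.44 in Ezh1-het and 0.38 in the double knockout against control. With loess it was 0.060, 0.052 and 0.0063. Median centring gave 6839 genes here (6668 higher, 171 lower). Changes are reported relative to the loess baseline. The calls of Cyth3 (-0.94, SE 0.23) and Fat3 (-0.87, SE 0.18) were lost without control 2 (-0.65 and -0.75) or Ezh2-KO 4 (-0.78 and -0.74), and that of Cyth3 also without Ezh2-KO 2 or 3 (-0.99 and -0.94). The calls of S100a8 (1.76, SE 0.42), S100a9 (2.44, SE 0.55) and Stfa1 (1.94, SE 0.41), genes of myeloid cells, were lost without control 2 (1.79, 2.40 and 1.90), and the first 2 also without Ezh2-KO 2 (1.91 and 2.55) or control 3 (1.65 and 2.17), S100a8 further without control 4 (1.81) or Ezh2-KO 3 (1.73). Beside them 0 of 14 macrophage and immune genes rose and 1, Cd74 (-0.50, SE 0.12), fell, a call lost without any of 5 single arrays (-0.54 to -0.39). The fall of Ibtk ended without control 2 (-0.67), the rise of Npy (0.60) and Meis1 (0.79) without Ezh2-KO 2, and that of Apcdd1 without control 2 (0.37) or Ezh2-KO 4 (0.37). Zfp931 (-0.78, SE 0.20), Foxm1 (0.71, SE 0.17) and Ier3 (0.64, SE 0.15) each depended on at least 5 single arrays, with values without them of -0.83 to -0.60, 0.59 to 0.71 and 0.53 to 0.64. Without both controls the calls of Cited1 (-0.51), Cstdc5 (1.89), Dlk1 (0.77), Ren1 (0.59), Nkd1 (0.51) and Lypd1 (0.42) ended too, and that of Hoxb5os ended with median centring (-0.37).

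In Ezh1-het kidneys the cell-cycle inhibitor Cdkn2a had the largest rise against control. It was at least 11.5-fold higher (log2 difference 3.52, SE 0.33, adjusted p = 2.43e-05) and above every control on all 4 arrays, and its neighbour Cdkn2b rose by 1.88 (SE 0.22, 3.68-fold, adjusted p = 0.000184). Ttr, a thyroid hormone carrier made by liver and choroid plexus, rose by 2.75 (SE 0.45), the protease gene Pappa2 by 2.51 (SE 0.46) and Bcl11a by 2.02 (SE 0.13). Lin28b was at least 3.97-fold higher (1.99, SE 0.12, adjusted p = 1.33e-07). Cited1 fell by 0.79 (SE 0.13, adjusted p = 0.00254), a call lost with median centring and with trend and robust variance, and Six2 was at -0.49 (SE 0.26, adjusted p = 0.252), Wnt4 at -0.01 (SE 0.16) and Lhx1 at 0.15 (SE 0.31).

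Podocyte genes rose as a list in Ezh1-het, with 9 of 21 higher and 1 lower (13 and 2 adjusted over the list alone), including Podxl (0.94, SE 0.20) and Thsd7a (0.96, SE 0.20). The camera adjusted p was 0.00217 (adjusted p = 0.297 with an estimated correlation), and the list stood 0.40 above other genes on slide 1 and 0.41 on slide 2. Among lists that were not called, liver was at 0.59 and 0.83 on slides 1 and 2, and loop of Henle at 0.25 and 0.73. Early nephron genes rose in 5 of 24 members (13 over the list alone, with 1 lower), with camera adjusted p = 0.000868 (adjusted p = 0.635 with an estimated correlation) and shifts of 0.21 on slide 1 and 0.80 on slide 2. Control 3 stood at -0.75 in this list and the other controls at 0.22 to 0.29. Without control 3 the shift was 0.27 in place of 0.50 (camera adjusted p = 0.0385). Of CDK inhibitors 4 of 8 rose (5 over the list alone), of p53 targets 7 of 20 (7), of Wnt/beta-catenin targets 7 of 17 (8) and of lineage transcription factors outside the kidney 12 of 41 (13). Among them were Pmaip1, the p53 target that encodes Noxa (1.64, SE 0.25), Zmat3 (0.75, SE 0.13), Rnf43 (1.37, SE 0.21), Wif1 (1.03, SE 0.11) and the midbrain homeobox gene En2 (1.84, SE 0.28). Camera adjusted p-values of the 4 lists were 0.000178, 0.00565, 0.00207 and 0.0170 (adjusted p of 0.104, 0.297, 0.104 and 0.681 with an estimated correlation), and their shifts on slides 1 and 2 were 0.84 and 0.87, 0.21 and 0.29, 0.28 and 0.46, and 0.16 and 0.15. The call of the lineage list was lost without control 1 (adjusted p = 0.105) or control 3 (adjusted p = 0.0893) and with no filter on dim probes (adjusted p = 0.238).

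The nephron progenitor list fell in Ezh1-het, with 5 of 22 lower and 1, Lypd1, higher (7 and 3 over the list alone, camera adjusted p = 0.000583, adjusted p = 0.635 with an estimated correlation). Crym fell by 0.90 (SE 0.17), a call lost with median centring. PRC2 subunits, with the deleted Ezh1 among them, fell as a list (2 of 11, Ezh1 and Aebp2, 2 over the list alone, camera adjusted p = 0.00220, adjusted p = 0.0854 with an estimated correlation), and proliferation genes rose (2 of 34, 2 over the list alone, 0.00565, adjusted p = 0.877 with an estimated correlation). On slides 1 and 2 the shifts of these 3 lists were -0.30 and -0.33, -0.31 and -0.29, and 0.15 and 0.08. Without control 3 the nephron progenitor shift was -0.20 in place of -0.31. The call of Aebp2 (-0.46, SE 0.13) was lost without control 2 (-0.36), 3 (-0.49) or 4 (-0.46) or Ezh1-het 2 (-0.37) or 4 (-0.39). It was also lost in 7 of 17 other settings, among them median centring (-0.0053) and the mean of its probes (-0.13). The call of the proliferation list was lost without control 2 (adjusted p = 0.108). Of the 38 Hox genes 5 rose and 2 fell (6 higher and 8 lower over the list alone), and the list was not called (camera adjusted p = 0.306). Hoxd13 (at least 2.20-fold) and Hoxa13 (at least 1.91-fold) rose, as did Pax9 (at least 1.56-fold). Among genes whose arrays did not overlap, the largest falls were in Mogat1, Nr1h5 (at least 2.45-fold lower), Zfyve1, Tmem25, Snord17, Ocm (-1.24, SE 0.13), Cyth3 (-1.18, SE 0.23) and Snora34. The falls of Mogat1 (-2.56, SE 0.72), Zfyve1 (-1.47, SE 0.41), Tmem25 (-1.38, SE 0.38), Snord17 (-1.29, SE 0.38) and Snora34 (-1.15, SE 0.32), and the rises of Klk1b5 (1.99, SE 0.57) and Klk1b26 (1.98, SE 0.53), paralogs whose signals may overlap, each ended without Ezh1-het 2 (-2.42, -1.43, -1.42, -1.27, -1.12, 1.98 and 1.98) or Ezh1-het 4 (-2.69, -1.54, -1.42, -1.05, -0.96, 1.97 and 1.93) and without at least 3 other single arrays.

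In total 1222 genes differed between Ezh1-het and control (925 higher, 297 lower, 523 by at least 1.5-fold; 957 with only the 2 groups fitted and 2217 with array weights), with no overlap of arrays for 17.9% of genes against 2.86% by chance. Without control 2, control 3, Ezh1-het 2, Ezh1-het 3 or Ezh1-het 4 the counts were 652, 755, 550, 795 and 487, and without both controls 235. The slide block gave 1390, slides 1 and 2 alone 138 and 37 with a correlation across genes of 0.66 (Spearman 0.61), and median centring 8037 (7745 higher, 292 lower). The calls of Pappa2 (1.79), Podxl (0.77) and Thsd7a (0.84) were lost without both controls.

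In double-knockout kidneys Cdkn2a was at least 19.4-fold higher than in controls (log2 difference 4.28, SE 0.33, adjusted p = 9.42e-07), and transcription factor genes were among the other rises. Hoxd13 was at least 5.52-fold higher (2.46, SE 0.12, adjusted p = 8.46e-09), Hoxb13 at least 4.87-fold (2.28, SE 0.17, 8.58e-07), Foxf1 of splanchnic mesoderm at least 3.26-fold (1.70, SE 0.09, 8.46e-09) and Hoxa13 at least 2.68-fold (1.42, SE 0.13, 4.14e-06). These 4 were not well above background on any control array and well above it on 4 of 4 double-knockout arrays. Ebf3 rose by 2.08 (SE 0.16), Bcl11a by 2.35 (SE 0.13), Miat by 2.39 (SE 0.29), Cdkn2b by 1.80 (SE 0.22, adjusted p = 0.000125) and the acute-phase gene Saa2 by 2.03 (SE 0.25).

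The list of lineage transcription factors outside the kidney holds 86 genes, of which 45 were not measured. A gene well above background on the 4 arrays of 1 group alone passes the filter, so the measured 41 are not an even sample of the list. Of these 23 rose and 0 fell (24 and 0 adjusted over the list alone, camera adjusted p = 1.07e-21, adjusted p = 0.00688 with an estimated correlation). The measured members stood 0.60 above other genes on slide 1 and 0.53 on slide 2, and with no filter on dim probes the shift was 0.32 in place of 0.57, and the call held. Of Hox genes 7 of 38 rose and 2 fell (7 and 4 over the list alone), with a median of -0.12, a mean of 0.11 and no call (camera adjusted p = 0.623). Among p53 targets 8 of 20 rose (12 over the list alone, camera adjusted p = 2.14e-10, adjusted p = 0.00688 with an estimated correlation), with Pmaip1 at 2.27 (SE 0.25), the cyclin gene Ccng1 at 1.15 (SE 0.18) and Zmat3 at 1.04 (SE 0.13). Their shift was 0.45 on slide 1 and 0.53 on slide 2. Of the CDK inhibitors 4 of 8 rose, among them Cdkn2c (1.00, SE 0.10), with camera adjusted p = 8.44e-07 (adjusted p = 0.0242 with an estimated correlation). Wnt/beta-catenin targets rose in 4 of 17 (6 over the list alone, camera adjusted p = 5.34e-05, adjusted p = 0.0242 with an estimated correlation), with Rnf43 at 1.11 (SE 0.21), Wif1 at 0.87 (SE 0.11) and Apcdd1 at 0.62 (SE 0.09). The calls of the lineage, p53, CDK inhibitor and Wnt lists held with an estimated correlation, and the shifts of the last 2 on slides 1 and 2 were 1.04 and 1.04, and 0.26 and 0.43. The PRC2 list was also called (camera adjusted p = 0.00271, adjusted p = 0.0242 with an estimated correlation), but it contains the deleted Ezh1, the only called member of 11, and its mean was -0.49 beside a median of -0.10.

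Proximal tubule genes were lower as a list in the double knockout (camera adjusted p = 2.57e-10, adjusted p = 0.405 with an estimated correlation), with 0 of 29 past limma's threshold over all genes and 10 lower adjusted over the list alone. Their mean per array was -1.01 ± 0.510 (SD, n = 4) against 0 ± 0.923 in controls. The shift was -1.45 on slide 1 and -0.59 on slide 2. Camera also called loop of Henle and distal tubule (0.00145), endothelium (0.00283), erythroid (0.00283) and skeletal muscle (0.0145) downwards and proliferation (5.47e-05), early nephron (0.0132) and immediate early genes (0.0290) upwards. With an estimated correlation the first 4 had adjusted p of 0.451, 0.451, 0.405 and 0.405, and the other 3 adjusted p = 0.555. On slides 1 and 2 the shifts were -0.71 and -0.18 for loop of Henle, -0.41 and -1.18 for erythroid, -0.20 and -0.25 for endothelium, -0.09 and -0.47 for skeletal muscle, 0.21 and 0.13 for proliferation, 0.03 and 0.40 for early nephron and 0.20 and 0.61 for immediate early genes. The erythroid shift was -0.44 without double knockout 4 in place of -0.79. The loop shift was -0.29 without control 2 and -0.72 without control 3 in place of -0.45. The proliferation shift was 0.10 without control 2 in place of 0.17. The early nephron call was lost without control 3 (adjusted p = 0.751) or double knockout 2 (0.0785), the immediate early call without control 4 (0.391) or double knockout 1 (0.0955), the skeletal muscle call without control 4 (0.0899). Within the early nephron list 4 of 24 rose, among them Npy (0.75, SE 0.14) and Pax8 (0.62, SE 0.11), while Wnt4 (-0.06, SE 0.16) and Lhx1 (-0.19, SE 0.31) did not pass. Called members of the other 6 lists numbered 0 of 34 for proliferation, 0 of 16 for immediate early, 0 of 21 for loop of Henle, 1 lower of 15 for endothelium (Ramp2), 0 of 8 for erythroid and 1 lower of 7 for skeletal muscle (Tnni2, -0.59, lost without double knockout 3 at -0.58). Adjusted over the list alone they were 3, 4, 0, 1, 4 and 1. At an unadjusted p under 0.05 limma gave 2678 genes in this comparison.

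The nephron progenitor list was not called in the double knockout (3 of 22 rose, 4 fell, camera adjusted p = 0.103), although Cited1 fell by 0.90 (SE 0.13, adjusted p = 0.000585) and Crym by 0.85 (SE 0.17), both lost with median centring (-0.31 and -0.16). Six2 was at -0.39 (SE 0.26, adjusted p = 0.496). The remaining lists had camera adjusted p of 0.0823 for stroma, 0.101 for nerve, 0.103 for liver, 0.427 for gonad, 0.464 for macrophage and immune, 0.669 for ureteric bud and collecting duct, 0.669 for tubular injury, 0.680 for sex-linked genes, 0.711 for adrenal and 0.711 for podocyte. In the germline list only 4 of 19 genes were measured, too few for the test, and Tdrd1 rose by 0.70 (SE 0.12). Single members also rose in uncalled lists, namely the stromal Dlk1 (1.72, SE 0.21), retinol-binding Rbp4 (1.76, SE 0.23) and the epithelial keratin Krt19 (1.27, SE 0.20). Among genes whose arrays did not overlap, the falls next to Ezh1 in size were in Trim46, Tmem25 (-1.996, SE 0.38), the small GTPase gene Arl16 (-1.63, SE 0.15), the fatty acid carrier Fabp4 (-1.51, SE 0.26), Ocm (-1.46, SE 0.13), Colq (-1.34, SE 0.17) and Wdfy1 (-1.31, SE 0.19). Trim46 (-3.87, SE 1.02) lost its call without control 1 (-3.50), control 2 (-2.61) or any of double knockouts 1 to 4 (-3.87, -3.84, -3.84 and -3.91). The calls of Tmem25 and Fabp4 ended with trend and robust variance, that of Ramp2 with median centring (-0.15) and that of Rnf43 without both controls (0.75).

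Double knockout and control differed in 723 genes (580 higher, 143 lower, 349 by at least 1.5-fold; 442 with only the 2 groups fitted and 1407 with array weights), with arrays not overlapping for 9.34% of genes against 2.86% by chance. Without double knockout 3 the count was 441, and without controls 2 and 3 it was 450. The slide block gave 806, slides 1 and 2 alone 229 and 113 with a correlation across genes of 0.69 (Spearman 0.59), and median centring 5364 (5191 higher, 173 lower).

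**Figure D1:**
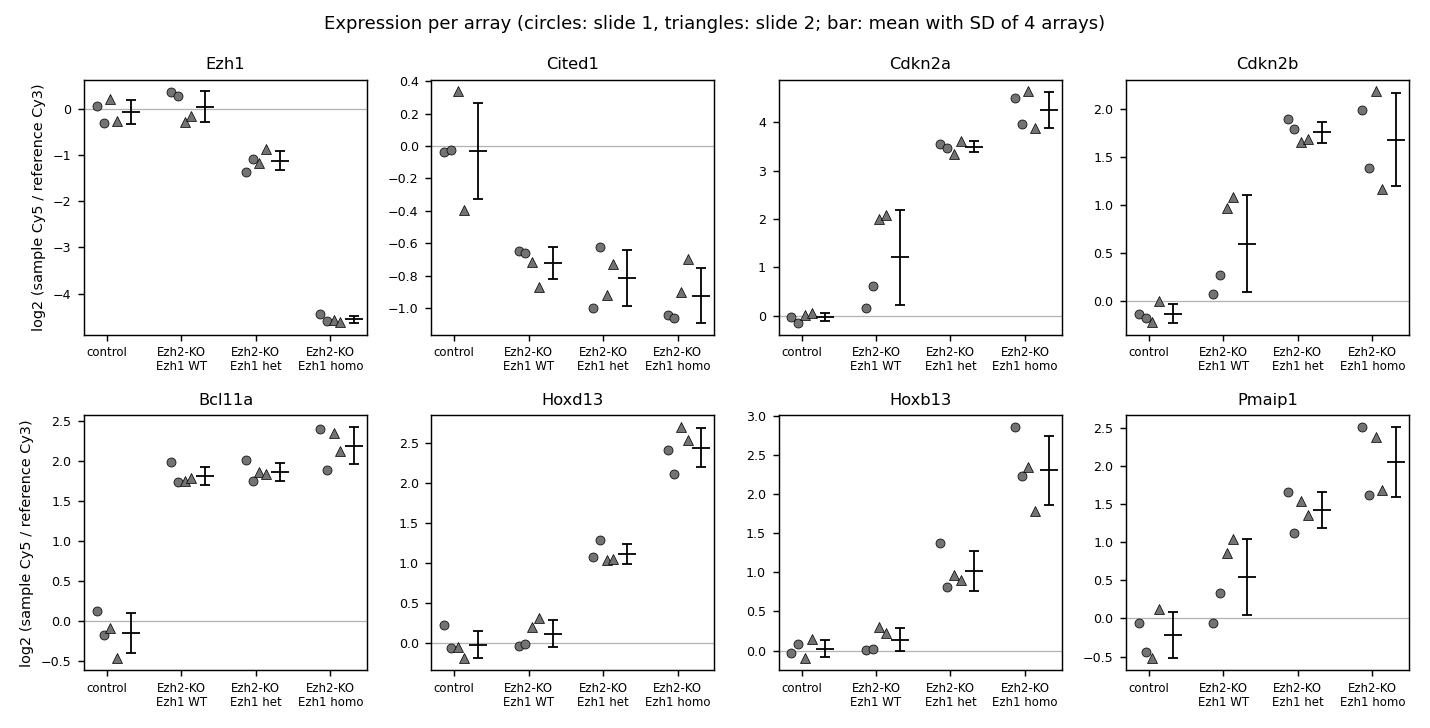
Log2 ratio of sample (Cy5) to reference (Cy3) per array for 8 genes, with circles for slide 1, triangles for slide 2 and a bar for the mean and SD of 4 arrays. Ezh1 averaged -4.55 in the double knockout, while Cdkn2a averaged 1.21, 3.50 and 4.25 in Ezh2-KO, Ezh1-het and double knockout and was split by slide in Ezh2-KO.

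The 3 knockout groups shared many called genes, and they also share their controls. Ezh2-KO and Ezh1-het had 278 higher and 84 lower genes in common, Ezh2-KO and double knockout 210 and 27, and Ezh1-het and double knockout 387 and 72. Independent lists of those sizes would share 22.2 and 2.01, 13.9 and 0.969, and 34.3 and 2.71. In 100 simulations of unchanged groups on shared controls the shared calls averaged at most 0.01. Noise was drawn for each gene on its own, so deviations of an array that many genes share were not simulated. With the controls split so that each comparison used 2 of its own, over 6 splits, the shared genes averaged 1.67 and 0.167, 1.5 and 0.167, and 128 and 16.2. Each of these fits held only the 2 controls and the knockout group, so fewer genes can pass than in the full fit. The fall in shared genes therefore does not measure the part due to shared controls. Correlations of the log2 differences across genes were 0.718, 0.650 and 0.576, where the simulations gave 0.500, 0.500 and 0.501, and split controls 0.410, 0.311 and 0.325. The covariances were 0.0506, 0.0425 and 0.0463, against 0.0120, 0.0121 and 0.0121 simulated, and with split controls 0.0327, 0.0246 and 0.0283. Bcl11a rose and Ocm fell in all 3 comparisons against control.

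What loss of both Ezh1 alleles adds to loss of Ezh2 was tested as the difference between double knockout and Ezh2-KO, where the controls enter only the shared spread. Ezh1 was lost in the germline, Ezh2 only in Six2-positive progenitors, and no group lost Ezh1 alone. Effects of Ezh1 loss in cells that keep Ezh2 and in cells that lack it therefore cannot be told apart. The same holds for the other comparisons between knockout groups and for the trend over Ezh1 alleles. The double knockout exceeded Ezh2-KO in Cdkn2a by 3.04 (SE 0.33, 8.21-fold, adjusted p = 7.47e-05), Hoxd13 by 2.33 (SE 0.12), Olfr224 by 1.63 (SE 0.09), the meiotic cohesin gene Rec8 by 1.60 (SE 0.22), Foxf1 by 1.59 (SE 0.09) and the hindlimb gene Pitx1 by 1.55 (SE 0.20). For Rec8 part of this difference lay in low Ezh2-KO values. Its arrays ran from -2.14 to -0.73 in Ezh2-KO and from -0.78 to -0.13 in controls. They ran from -0.45 to -0.09 in Ezh1-het and from 0.06 to 0.22 in the double knockout. Hoxb13 was at least 4.50-fold higher than in Ezh2-KO (2.17, SE 0.17, adjusted p = 2.69e-06). The Cdkn2a call was lost with the processed signals and with the value table (adjusted p of 0.0555 and 0.0554). Lineage transcription factors outside the kidney rose in 18 of 41 members (25 over the list alone, camera adjusted p = 9.79e-37, adjusted p = 0.00136 with an estimated correlation) and p53 targets in 5 of 20 (11 over the list alone, 2.07e-11, adjusted p = 0.00452 with an estimated correlation), such as Pmaip1 (1.504, SE 0.25), Ccng1 (1.08, SE 0.18) and Zmat3 (0.77, SE 0.13). The calls of these 3 genes ended with only the 2 groups fitted, and that of Zmat3 with median centring (0.83). Pmaip1 values in Ezh2-KO were -0.05 and 0.34 on slide 1 and 0.86 and 1.04 on slide 2. CDK inhibitors rose in 4 of 8 (camera adjusted p = 3.58e-06, adjusted p = 0.0525 with an estimated correlation), including Cdkn2c (1.08, SE 0.10). On slides 1 and 2 the lineage list shifted by 0.66 and 0.51, p53 targets by 0.40 and 0.44 and CDK inhibitors by 0.99 and 0.58. Hoxa13 rose by 1.35 (SE 0.13), and of 38 Hox genes 5 rose and 0 fell (7 and 4 over the list alone, camera adjusted p = 0.219).

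Below Ezh2-KO in the double knockout, after Ezh1 (-4.60, SE 0.15), were S100a9, Cstdc5, Fabp4 (-2.002, SE 0.26), Arl16 (-1.93, SE 0.15), Stfa1, the endothelial adhesion gene Icam2 (-1.35, SE 0.27) and Serpina6. Endothelium genes were lower as a list (0 of 15 called, 8 over the list alone, camera adjusted p = 0.000196, adjusted p = 0.355 with an estimated correlation), as were erythroid (0 of 8, 6 over the list alone, 0.000723, adjusted p = 0.355), proximal tubule (0 of 29, 0.00148, adjusted p = 0.796) and loop of Henle genes (0 of 21, 1 over the list alone, 0.00298, adjusted p = 0.618 with an estimated correlation). Camera called the liver list upwards, with 1 of 9 members past limma's threshold, Rbp4 (1.02, SE 0.23, lost without 6 of the 8 single arrays, at 0.74 to 1.04). Its camera adjusted p was 0.0419 (adjusted p = 0.619 with an estimated correlation), with a shift of 0.86 on slide 1 and -0.31 on slide 2, and the call ended without Ezh2-KO 1 or 2 (0.306 and 0.0911) or double knockout 1 or 3 (0.173 and 0.114). The endothelium shift was -0.07 on slide 1 and -0.54 on slide 2, and the erythroid shift -0.48 and -1.54. Without Ezh2-KO 3 the endothelium shift was -0.18 in place of -0.31. Without double knockout 4 the erythroid shift was -0.65 in place of -1.01. The proximal tubule and loop calls were lost without Ezh2-KO 4 (adjusted p of 0.232 and 0.0946) or double knockout 4 (0.154 and 0.0631), and their shifts were 0.04 and 0.07 on slide 1 and -1.19 and -1.03 on slide 2. Without Ezh2-KO 1 their shifts over both slides were larger, at -0.87 and -0.72 in place of -0.58 and -0.48. Cited1 (-0.20, SE 0.13), Six2 (-0.32, SE 0.26), Wnt4 (-0.34, SE 0.16) and Lhx1 (-0.20, SE 0.31) did not pass. Cdkn2b exceeded Ezh2-KO by 1.08 (SE 0.22, adjusted p = 0.0316), a call lost without Ezh2-KO 1 or 2 (0.90 and 0.97) or double knockout 1 or 3 (0.98 and 0.91). That call was also lost with the processed signals (1.87), the value table (1.86), the replicate number as a block (1.08), only the 2 groups (1.08) and the mean of the probes (0.98). The falls of S100a9 (-2.64, SE 0.55), Cstdc5 (-2.13, SE 0.42), Stfa1 (-1.92, SE 0.41), Icam2 and Serpina6 (-1.30, SE 0.29) ended without double knockout 2 (-2.60, -2.16, -1.86, -1.36 and -1.24) or 4 (-2.46, -2.05, -1.85, -1.25 and -1.24), all but Icam2 also without double knockout 3 (-2.57, -2.04, -1.90 and -1.41), S100a9, Cstdc5 and Stfa1 without Ezh2-KO 3 (-2.63, -2.09 and -1.86), S100a9, Stfa1 and Serpina6 without Ezh2-KO 2 (-2.75, -2.06 and -1.18). All 5 falls ended with only the 2 groups fitted, and those of S100a9, Stfa1 and Serpina6 with the processed signals (-4.11, -4.55 and -3.10). In all 143 genes differed (100 higher, 43 lower), 66 with only the 2 groups fitted and 699 with array weights, with no overlap for 7.57% of genes against 2.86% by chance, and 84, 87 and 91 without Ezh2-KO 2, double knockout 2 or double knockout 3. With the slide block 156 genes differed, within slides 1 and 2 alone 133 and 13, and the slides correlated across genes at 0.04 (Spearman 0.03).

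Between Ezh1-het and Ezh2-KO 9 genes differed (6 higher, 3 lower), 3 with only the 2 groups fitted and 218 with array weights. Another split of the same 8 arrays gave 25. Of the genes named throughout, Cdkn2a was higher by 2.28 (SE 0.33, 4.87-fold, adjusted p = 0.01001) and Ezh1 lower by 1.18 (SE 0.15, adjusted p = 0.00535). Cdkn2b was at 1.15 (SE 0.22, adjusted p = 0.123). The Cdkn2a difference was 3.13 on slide 1 and 1.44 on slide 2, and its call was lost without Ezh2-KO 2 (2.08), Ezh1-het 2 (2.30) or Ezh1-het 4 (2.24), and with the processed signals (2.77), the value table (2.76) or only the 2 groups (2.28). The Ezh1 call was lost with median centring (-1.16), with only the 2 groups and with trend and robust variance (-1.18 each). Camera called 10 lists, 7 upwards and 3 downwards, and with an estimated correlation it called 0. Podocyte genes were higher (camera adjusted p = 2.23e-08, 11 higher over the list alone, adjusted p = 0.0552 with an estimated correlation), with 0 of 21 past limma's threshold over all genes, where 1154 genes had an unadjusted p under 0.05. Their shift was 0.57 on slide 1 and 0.18 on slide 2. Proximal tubule genes stood 1.31 above other genes on slide 1 and 0.07 on slide 2 (camera adjusted p = 1.32e-08, adjusted p = 0.536 with an estimated correlation). The other lists called upwards were CDK inhibitors (7.36e-07), lineage transcription factors (7.46e-07), liver (0.00115), p53 targets (0.00235) and loop of Henle (0.00334), with adjusted p of 0.0552, 0.233, 0.413, 0.233 and 0.537 with an estimated correlation. On slides 1 and 2 these shifted by 0.80 and 0.42, 0.22 and 0.12, 1.12 and 0.09, 0.17 and 0.20, and 1.03 and -0.12. Immediate early (0.000289), nephron progenitor (0.00154) and macrophage genes (0.0106) were called downwards, with adjusted p of 0.431, 0.537 and 0.555 with an estimated correlation and shifts on slides 1 and 2 of -0.90 and 0.10, -0.45 and 0.03, and -0.16 and -0.39. Leaving out Ezh2-KO 1 brought the shift of proximal tubule genes from 0.69 to 0.39, of liver from 0.61 to 0.38, of immediate early from -0.40 to -0.24 and of nephron progenitor genes from -0.21 to -0.12. The loop call ended without Ezh2-KO 1 (0.0576) or Ezh1-het 1 (0.0631), and the macrophage call without Ezh1-het 1 (0.0637), Ezh2-KO 3 (0.301) or Ezh1-het 4 (0.188). Leaving out Ezh2-KO 2, 3 or 4 gave 3, 5 and 35 genes and leaving out Ezh1-het 2, 3 or 4 gave 4, 5 and 4. The slide block gave 10, slides 1 and 2 alone 879 and 3 with a correlation across genes of 0.01 (Spearman -0.05), and median centring 7 (7 higher, 0 lower).

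For loss of the second Ezh1 allele, double knockout against Ezh1-het, camera gave its smallest adjusted p for lineage transcription factors outside the kidney. Proximal tubule genes shifted more, as given below, but only the lineage list was also called with an estimated correlation. Members of the lineage list can pass the filter through double-knockout arrays alone, here and against Ezh2-KO. Of its measured members 12 of 41 rose (18 over the list alone, camera adjusted p = 1.82e-22, adjusted p = 0.0119 with an estimated correlation), by 0.44 relative to other genes on slide 1 and 0.38 on slide 2. Ezh1 fell by 3.42 (SE 0.15, adjusted p = 3.45e-09). Cdkn2a was at 0.75 (SE 0.33, adjusted p = 0.321), Cdkn2b at -0.07 (SE 0.22, adjusted p = 0.932) and Cited1 at -0.11 (SE 0.13, adjusted p = 0.803). Hox genes rose as a list (4 of 38, 6 higher and 2 lower over the list alone, camera adjusted p = 0.000932, adjusted p = 0.501 with an estimated correlation). Camera also called proximal tubule (0 of 29, 24 lower over the list alone, 8.52e-16), loop of Henle (1 of 21, 10 over the list alone, 8.82e-08), podocyte (0 of 21, 9 over the list alone, 2.45e-05), erythroid (9.37e-05) and endothelium genes (0.0126) downwards and p53 targets (4.63e-06), nephron progenitor (0.00211) and immediate early genes (0.0121) upwards. In that order they had adjusted p of 0.264, 0.264, 0.160, 0.264, 0.589, 0.0613, 0.589 and 0.589 with an estimated correlation. The endothelium call ended without Ezh1-het 2 (0.0710) or double knockout 4 (0.0584), immediate early without Ezh1-het 2 (0.0712) or double knockout 1 (0.0692), and nephron progenitor without Ezh1-het 1 (0.0530) or double knockout 4 (0.0584). Shifts on slides 1 and 2 were -1.28 and -1.26 for proximal tubule, -0.96 and -0.91 for loop of Henle, -0.36 and -0.36 for podocyte, -0.72 and -1.34 for erythroid, -0.19 and -0.19 for endothelium, 0.20 and 0.17 for Hox, 0.24 and 0.24 for p53, 0.17 and 0.19 for nephron progenitor and 0.47 and 0.26 for immediate early genes. The erythroid shift was -0.67 without double knockout 4 in place of -1.03. In all 59 genes differed (37 higher, 22 lower), 1033 (155 higher, 878 lower) with only the 2 groups fitted and 749 with array weights, with no overlap for 12.7% of genes against 2.86% by chance. The count rose to 285, 148 and 156 without control 3, Ezh2-KO 1 or Ezh2-KO 4, which enter only the shared spread, and was 29, 26, 35 and 32 without Ezh1-het 1 to 4 and 31, 34, 30 and 37 without double knockout 1 to 4. The slide block gave 48, slides 1 and 2 alone 34 and 3 with a correlation across genes of 0.76 (Spearman 0.51), and median centring 50 (37 higher, 13 lower).

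**Figure D2:**
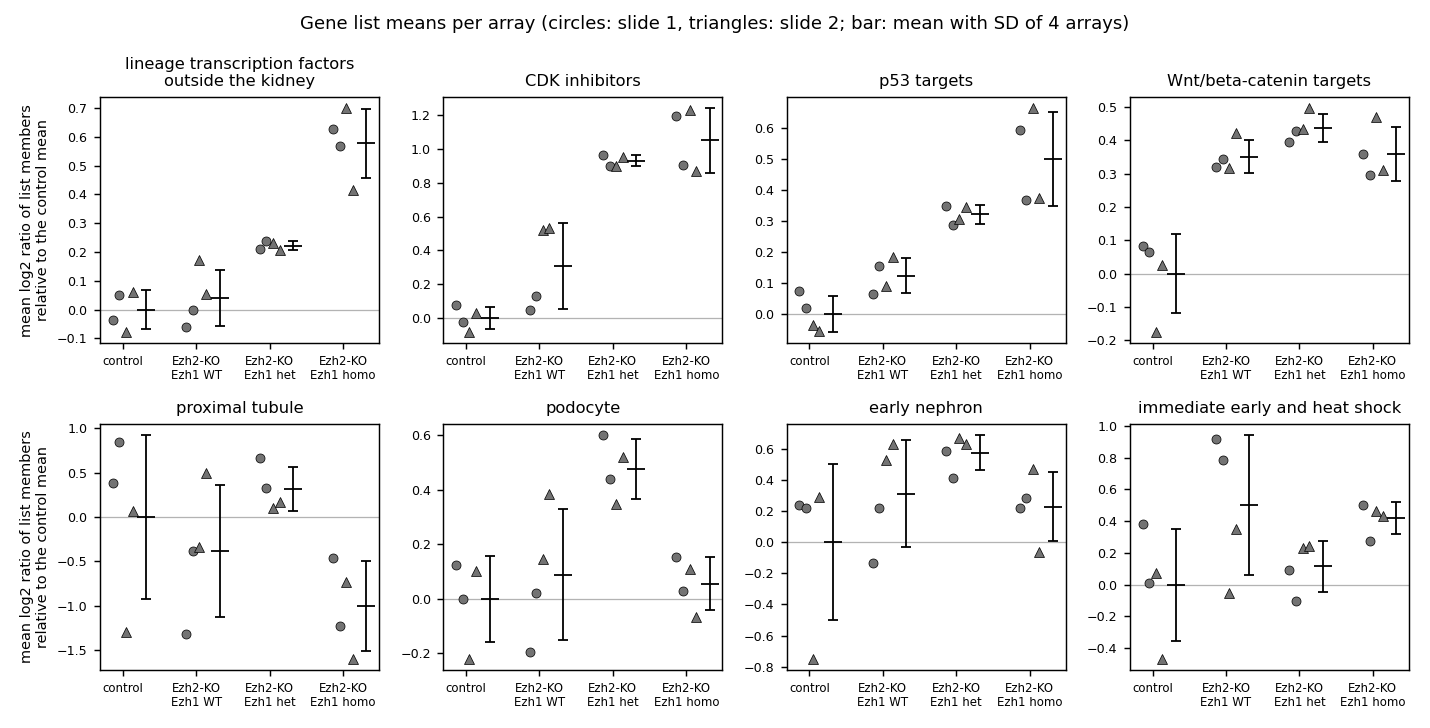
Mean log2 ratio of the measured members of 8 gene lists on each array, relative to the control mean, with circles for slide 1, triangles for slide 2 and a bar for the mean and SD of 4 arrays. The lineage list averaged 0.04, 0.22 and 0.58 in Ezh2-KO, Ezh1-het and double knockout, while control arrays spread from -1.30 to 0.84 in proximal tubule genes.

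Across the 12 Ezh2-deficient arrays 116 genes had a called slope over the number of Ezh1 alleles lost, 85 upwards and 31 downwards (355 with array weights). The slope averages 2 steps that need not be equal: Cdkn2a moved by 2.28 and then 0.75, and Ezh1 by -1.18 and then -3.42. Hoxd13 rose by 1.16 per allele (SE 0.06), Hoxb13 by 1.08 (SE 0.10), Hoxa13 by 0.68 (SE 0.07), Cdkn2c by 0.54 (SE 0.04) and Cdkn2a by 1.52 (SE 0.21), and Arl16 fell by 0.96 (SE 0.05), beside Ezh1 itself with a fall of 2.30 (SE 0.19). The count was 66, 65 and 62 without Ezh2-KO 2, double knockout 1 or double knockout 3.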

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

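The weighing of the genes near Ezh1, of the Ezh2 probes and of the proximal tubule genes used tests chosen after those results were seen, while the tests of single arrays that stand apart and the splits of the samples were planned.

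Of 500 groups of 4 arrays tested, 26 had 1 array far from the other 3, 20 in named genes and 6 in gene lists, and chance alone gives about 1 in 20 such groups. Control 3 stood apart in Fgf9 (-0.74, others -0.11 to 0.01), Robo2 (0.45, others -0.05 to 0.00), S100a8 (-0.49, others -0.07 to -0.00) and in the early nephron (-0.75, others 0.22 to 0.29), liver (-0.69, others 0.16 to 0.27) and tubular injury lists (-0.71, others 0.19 to 0.29). Lin28b was at 0.14 on control 4 (others -0.24 to -0.19) and Rbp4 at -0.067 on control 1 (others -0.40 to -0.38).

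In the Ezh2-KO group, array 4 stood apart in Gfra1 (-0.028, others 0.25 to 0.26) and Lypd1 (0.48, others 0.24 to 0.28), array 1 in Ocm (-0.69, others -1.11 to -1.06) and array 3 in Wif1 (0.44, others 0.85 to 0.88). In the Ezh1-het group, array 1 stood apart in Foxm1 (-0.37, others 0.19 to 0.25), Ramp2 (-0.93, others -0.59 to -0.53), the liver list (1.02, others 0.69 to 0.71) and the proliferation list (0.027, others 0.22 to 0.26), array 2 in Hoxd13 (1.29, others 1.04 to 1.07), array 3 in Cyth3 (-0.65, others -0.99 to -0.94), Krt19 (0.21, others 0.67 to 0.71), Tmem25 (-1.96, others -1.57 to -1.51) and Zfp931 (0.12, others -0.36 to -0.31), and array 4 in Pax9 (0.56, others 0.67 to 0.68) and Zmat3 (0.67, others 0.50 to 0.52). In the double knockout, array 4 stood apart in Hoxa13 (1.11, others 1.57 to 1.66) and the tubular injury list (-0.31, others 0.22 to 0.29), and array 2 in Wdfy1 (-0.62, others -1.24 to -1.14). Among probes without a gene symbol, which entered only the count of probes tested separately, 222 of 11869 passed limma's threshold in double knockout against control.

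Arl16, on the chromosome of Ezh1 in the reference table, fell with the number of Ezh1 alleles lost, and its other probe was also lower, at -1.78 in the double knockout, which argues against a variant under a single probe. Among the 50 measured genes on each side of Ezh1, 1 followed the trend (Krt36), as many as in 46.4% of such windows around other genes. A test of whole chromosomes, chosen after that count, found 19 trend genes on chromosome 11 besides Ezh1, where 9.56 were expected from its number of tested genes (hypergeometric test, adjusted p = 0.0320), but chromosome 13 also had 12 against 4.24 (adjusted p = 0.0241). DNA of another strain carried along with the targeted allele may therefore account for part of the 19, and 96 trend genes lay on other chromosomes, where loss of Ezh1 is a candidate explanation. Both stay open, since no strain or genotype beyond the labels was tested. The hypergeometric test also counts genes as independent. Hoxb13, Gm11538, Hoxb9 and Hoxb5os, all among the 19, lie close together, so its p-values may be too small.

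The Ezh2 probe A_51_P248067 differed by -3.41, -3.53 and -3.19, a range of 0.343 over the 3 knockout groups, while the other 4 Ezh2 probes differed by -0.22 to -0.58. It was well above background on 4 of 4 control arrays, which argues against a probe that reads no signal. A deleted part of the transcript that only this probe reads, or a strain variant under it, could each give a like fall in every knockout group, and the range of 0.343 cannot separate them. Cells that do not come from Six2-positive progenitors keep the whole transcript, so a deletion would leave their share of the signal. The probe kept 9.39%, 8.66% and 10.99% of its control signal, and the share of such cells was not measured. Probe positions were not used here either, so both stay open.

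Proximal tubule genes varied within genotypes, from -1.30 to 0.84 among controls. Tissue handling or developmental timing may differ between samples. The immediate early score can bear on handling at most, as it does not measure developmental timing, which was not tested. Within groups that score had Pearson r = -0.212 (permutation p = 0.563, adjusted 0.696) and Spearman rho = -0.271 (p = 0.394, adjusted 0.788) with the proximal tubule score over 16 arrays, and r = -0.276 without the 2 farthest. Strength of the Cy5 signal had r = -0.163 (permutation p = 0.696, adjusted 0.696) and rho = 0.0765 (p = 0.815, adjusted 0.815), and r = 0.557 without the 2 farthest. For genotype, double knockout against control gave an exact permutation p = 0.143 over 70 splits. These 2 correlations and this test left all 3 explanations open, and genotype was tested only against control. The double-knockout arrays ran from -1.60 to -0.46 and lay below all Ezh1-het arrays (0.10 to 0.67), while the Ezh2-KO arrays spread from -1.32 to 0.50.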

How the results depend on the processing

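The fits without controls 2 and 3 and with the immediate early score were chosen after seeing the data, and the other settings were planned. Across settings 299 counts and agreements stayed near their value and 86 moved further. Counts were judged by a factor of 1.5, and agreements between slides by a fixed difference in correlation. Of list shifts 674 kept direction and side of the threshold and 123 were no longer called. Of named gene values 4336 kept both, 498 were no longer called, 22 became called and 49 changed sign. Calls of named genes that held in every setting numbered 7 of 33 in Ezh2-KO, 21 of 58 in Ezh1-het and 31 of 47 in double knockout against control, 13 of 27 in double knockout against Ezh2-KO, 0 of 2 in Ezh1-het against Ezh2-KO and 1 of 1 in double knockout against Ezh1-het. The cause was not tested except where stated. Signal over background, lowest on control 2, limits dim probes. Aquantile scaling leaves the ratio as it is, so that setting could not differ.

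Comparisons are given in the order Ezh2-KO, Ezh1-het and double knockout against control, double knockout against Ezh2-KO, Ezh1-het against Ezh2-KO, double knockout against Ezh1-het, where the counts were 482, 1222, 723, 143, 9 and 59. With array weights they were 879, 2217, 1407, 699, 218 and 749, and 355 for the trend over Ezh1 alleles. Median centring gave 6839, 8037 and 5364 in the first 3, a minimum fold of 1.5 gave 220, 523 and 349, and leaving out controls 2 and 3 gave 78, 235 and 450. Only the groups compared gave 59 in the first, 442 in the third and 66, 3 and 1033 in the last 3; the trend has no such setting. Each probe separately gave 913 and 2206 in the first 2, 234 in the fourth and 207 for the trend. Probes well above background on all arrays gave 48, 1 and 4 in the last 3 and 38 for the trend, with fewer genes tested. The immediate early score gave 184 in the first and 3 in Ezh1-het against Ezh2-KO, where trend and robust variance gave 5. Double knockout against Ezh1-het had 37 with processed signals, 35 with the value table and 110 with Cy5 alone, and the trend 177 with Cy5 alone. Agreement between slides in double knockout against Ezh2-KO was 0.150 with processed signals. With controls split, and so fewer arrays in each fit, the shared calls were 1.83, 1.67 and 144. Leaving out single arrays gave 201 to 515, 487 to 1484, 441 to 922, 84 to 199, 3 to 35 and 26 to 285 genes, and 62 to 147 for the trend. Median centring leaves a difference of the ratio between the brightest and dimmest spots, which loess removes. It was -0.30 on control 2, up to 0.73 on the other controls and 0.76 to 1.39 on the knockout arrays. Controls and knockouts did not overlap, so what loess removes differs between them and cannot be told apart from genotype here.

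Camera called 5, 9, 13, 8, 10 and 10 lists, with an estimated correlation 0, 0, 5, 2, 0 and 1. Fry called 1 in Ezh2-KO, 6 in double knockout against control, and 4, 3 and 6 in the last 3. Leaving out single arrays gave 3 to 7 in Ezh2-KO against control.

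Genes that changed sign did so with median centring against control: Ezh2 (0.27, 0.26 and 0.33), Six2 (0.52, 0.19 and 0.31), Wnt4 (0.67 in Ezh1-het, 0.60 in double knockout), Gfra1 (0.12) and Ramp2 (0.085) in Ezh1-het, and Lhx1 (0.43) in double knockout. With Cy5 alone they were Wnt4 (0.18 and 0.048 in Ezh1-het and double knockout), Ezh2 in Ezh1-het against Ezh2-KO (0.022), and Cited1 (0.019) and Cdkn2b (0.079) in double knockout against Ezh1-het. With array weights they were Six2 (0.20) and Lhx1 (-0.031) in Ezh2-KO, Wnt4 (0.086 and 0.033), Ezh2 in double knockout against Ezh2-KO (-0.024), and Six2 (-0.075) and Cdkn2b (0.16) in double knockout against Ezh1-het. The mean of the probes of Ezh2 gave -0.00897 in double knockout against Ezh2-KO. Without controls 2 and 3 they were Six2 (0.22) and Lhx1 (-0.077) in Ezh2-KO and Wnt4 (0.088 and 0.035). Of these, Gfra1 and Ramp2 were called in the main fit. With median centring, Wnt4 in Ezh1-het (limma adjusted p = 0.0286) and Ezh2 in double knockout (limma adjusted p = 0.0484) were called higher than control. Leaving out single arrays gave Six2 -0.25 to 0.13 and Lhx1 -0.33 to 0.30 in Ezh2-KO, Wnt4 -0.093 to 0.070 and Lhx1 -0.20 to 0.43 in Ezh1-het, Wnt4 -0.13 to 0.074 and Lhx1 -0.53 to 0.10 in double knockout, Ezh2 -0.042 to 0.099 in double knockout against Ezh2-KO, Lhx1 -0.0032 to 0.25 in Ezh1-het against Ezh2-KO, and Six2 -0.075 to 0.27, Wnt4 -0.13 to 0.086 and Cdkn2b -0.24 to 0.096 in double knockout against Ezh1-het.

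With the replicate number as a block the counts were 462, 1125, 740, 122, 4 and 41 genes and 4, 9, 13, 8, 11 and 10 lists, and 13 calls of named genes were lost. The numbers do not pair the samples: 24 same-numbered pairs correlated at -0.478 to 0.514 (median 0.0167, other pairs -0.00237), and 5 of 16 samples correlated best with their own number. The slide as a fixed block ended 1 call of a named gene (Tdrd1 in double knockout against Ezh2-KO), and as a random block had a correlation of 0.0137.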

Other observations

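The genes of the next paragraph and the test of the reference channel were chosen after their values were seen, and the splits of the samples were planned.

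Among the 116 genes with a called slope over the number of Ezh1 alleles lost in the 12 Ezh2-deficient arrays were further transcription factors, picked by hand, and their share was not tested. Per allele, Onecut2 rose by 0.63 (SE 0.06), Shox2 by 0.49 (SE 0.06), Prrx1 by 0.48 (SE 0.07), Vax2 by 0.44 (SE 0.05), Tbx15 by 0.41 (SE 0.05), Tbr1 by 0.33 (SE 0.04) and Foxa2 by 0.58 (SE 0.08), and the non-coding Fendrr by 0.40 (SE 0.06).

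The X-inactivation transcript Xist varied within groups, at -1.10 ± 1.32 (SD, n = 4) in controls, -1.68 ± 0.42 in Ezh2-KO, -2.20 ± 1.28 in Ezh1-het and -1.31 ± 1.29 in the double knockout, and the sex of the embryos was not used here.

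The Cy3 channel held the same control RNA on every array, and its level after loess and scaling between arrays was tested. Loess follows the mean of both channels, so this Cy3 level depends in part on the Cy5 signal. The test gave 0, 51 and 81 genes for Ezh2-KO, Ezh1-het and double knockout against control, 52 for double knockout against Ezh2-KO, 0 for Ezh1-het against Ezh2-KO and 7 for double knockout against Ezh1-het (limma, with 759, 3391, 1736, 893, 1681 and 1931 genes at an unadjusted p under 0.05). Cdkn2a differed by 0.58 in that level beside 4.28 in the ratio, and Hoxd13 by 0.47 beside 2.46. Whether the Cy3 signal before loess differed was not tested.

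Over the 35 splits of the 8 arrays compared, the real split alone gave the most genes in the comparisons that follow. They were Ezh1-het against control (1222, highest other 0) and double knockout against control (723, highest other 1). The others were double knockout against Ezh2-KO (143, highest other 0) and double knockout against Ezh1-het (59, highest other 1). The real split is 1 of the 35, so its share cannot be smaller than 1 in 35. This share was not adjusted over the comparisons, so these splits cannot exclude chance. Another split gave more genes for Ezh2-KO against control (2 splits with as many, 482, highest other 654). The same held for Ezh1-het against Ezh2-KO (2 splits, 9, highest other 25), so chance was not excluded there either. For the trend over Ezh1 alleles 1 of 100 groupings gave as many (116, highest other 50), and that 1 is the real grouping. This share was not adjusted over the tests either, so chance was not taken as excluded. For the number of lists called it was not excluded in any comparison: 25 splits gave as many as the 5 lists of Ezh2-KO against control (highest other 14), 9 as many as the 9 of Ezh1-het (15), 3 as many as the 13 of the double knockout (15), 16 as many as the 8 of double knockout against Ezh2-KO (16), 9 as many as the 10 of Ezh1-het against Ezh2-KO (13) and 6 as many as the 10 of double knockout against Ezh1-het (14).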
